A study of Mus musculus with 2 samples.

How the data were processed

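Total RNA from mouse fetal palate at E18.5 (embryonic day) was labelled as biotinylated cRNA from 6 µg per sample and hybridised to Affymetrix expression arrays, per the labels' protocols. There were 2 samples of the BALB/c background, 1 array of wild-type palate and 1 array of palate labelled as carrying null alleles of both Myf5 and MyoD (gene symbol Myod1). The labels do not say whether a sample was 1 fetus or a pool, nor which part of each targeted gene was removed.

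The deposited values were linear signal intensities, 1 per probe set, computed by the authors with MAS5, per the submitters' processing notes; the version is not given in the sources used here. Each array listed 45101 probe sets, of which 64 were Affymetrix controls. The trimmed mean that leaves out 2% of probe sets at either end was 1500.01 on both arrays, as it is where arrays are scaled to a common target. Detection calls were not used here. No genome build is named in the files, so no coordinates are given.

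Probe sets were named through the platform annotation, in which 34945 probe sets had 1 gene, 932 had several and 9160 had no listed gene. Probe sets of several genes or of none were left out of gene counts. Gene identifiers of 34741 probe sets were found in the RefSeq table of assembly GRCm38.p6, and no symbol changed. A gene without a listed probe set was not analysed here.

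Each array was divided by the median of the probe sets that lay at or above the 50th percentile on both arrays, and both were multiplied by the geometric mean of those medians, which gave factors of 0.974 for the wild-type array and 1.03 for the other. Signals under the 40th percentile of all scaled values (287) were then set to that floor, and log2 was taken. All ratios are the array labelled double null over the wild-type array, as differences of log2 signals. Where one array was under the floor, the fold is a lower bound and is written with "at least". A gene was represented by its probe set with the highest mean log2 signal and counted as measured where its brighter array reached the 60th percentile (658), which left 11238 of 18193 genes. Control probe sets were left out of all gene results.

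With 1 array per genotype no test between genotypes was possible, and no p-value is given. The number of arrays limits the precision: differences between animals, dissections and hybridisations cannot be separated from genotype. As a measure of spread within these arrays, the log2 ratios of different probe sets of the same gene had a pooled SD of 0.51, from 10190 measured probe sets of 4030 genes. This covers probe and isoform effects and not differences between animals. Genes were counted by a rule of size, at least 2-fold. For each of 38 gene lists the median log2 ratio was set as a percentile among 10000 random lists of the same size matched on mean log2 signal in 20 bins, which describes these arrays only. The range given for random lists is their central 95%.

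The scaling, floor, filter, gene lists and rule for named genes were fixed before the data were examined. The named genes were Myf5 and Myod1, the 15 genes with the lowest and the 15 with the highest ratio among those whose brighter array reached the 75th percentile (1479), and up to 4 measured members of each list with the largest absolute ratio (12 for the palatogenesis list), plus the member that went furthest the other way from its list. Genes named outside that rule are said to be so. Alternatives were the deposited scaling, quantile normalization, scaling on reference genes, other floors, an added offset, no floor, the mean over all measured probe sets, probe sets without cross-hybridising suffixes, other filters, 1.5-fold and 3-fold rules, and random lists matched on the wild-type signal.

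The steps were tested on simulated data made from these arrays, with 200 genes of the comparison between the arrays changed by known ratios and noise set to the SD between probe sets. A simulated log2 ratio of 3.00 was recovered with a median of 2.98 and one of -3.00 with a median of -2.56. All simulated genes of those sizes passed 2-fold, as did 78.0% at a log2 ratio of 1.50 and 82.6% at -1.50. Among 10911 genes simulated without change, 5.58% passed 2-fold, and 2.00% of 200 unchanged lists of 20 genes fell outside the random range. Analyses were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.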

Results

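Gene expression was measured in the palate of BALB/c mouse fetuses at E18.5 (embryonic day), with 1 array for wild-type palate and 1 array for palate labelled as lacking both Myf5 and MyoD. These are the basic helix-loop-helix transcription factors that commit cells to the skeletal muscle lineage. The series was made to ask what skeletal muscle contributes to palate development, and the design holds 1 comparison, that of the genotypes. There were no replicates, so every difference below is between these 2 arrays and carries no p-value. Deposited MAS5 signals ran from 1.26 to 171378 on the wild-type array and from 0.98 to 193166 on the other. Across the 11238 measured genes, log2 signals of the arrays had a Pearson correlation of 0.933 (across genes, which are not replicates), and 92.3% of genes lay within 2-fold.

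The targeted genes did not separate the arrays. The measured Myod1 probe set had a signal of 1938 in wild type and 1663 on the array labelled double null, a log2 ratio of -0.22 that is smaller than the SD of 0.51 between probe sets of one gene. A dimmer Myod1 probe set gave 282 and 305. The only Myf5 probe set gave 517 and 531, below the level at which a gene counted as measured. Neither the labels nor the annotation place these probe sets inside or outside the removed parts of the genes. The Myod1 value would go against the label if its probe set lies in a removed part. Outside it, the probe set could read a transcript left by the null allele, so the Myod1 value alone does not decide whether the label is right. The second array is therefore called the array labelled double null throughout.

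Genes of the contractile apparatus were mostly lower on the array labelled double null, and most of them stayed bright. The sarcomere list had a median log2 ratio of -0.76, or 1.70-fold lower, and 36 of its 37 measured genes were below 0. Of these, 11 were at least 2-fold lower, none was at least 2-fold higher, and 26 lay in between; the count at least 2-fold lower was 4 of 36 with scaling on the median signal of the reference genes and 17 of 37 with scaling on their median ratio. Tnnc2, fast skeletal troponin C, had signals of 31028 and 9596 (3.23-fold lower). Tnni1, slow skeletal troponin I, was 2.71-fold lower, Des, the muscle intermediate filament desmin, 2.90-fold lower, and Mybph at least 2.73-fold lower. Nebl was the 1 sarcomere gene above 0, with a log2 ratio of 0.22. The median lay below that of all 10000 matched random lists, whose range was -0.08 to 0.27. In the 9 sarcomere genes with another measured probe set, the other probe sets were lower in all 9, whereas over all skeletal muscle lists the other probe sets were below 0 in 12 of 23 genes and above 0 in 11.

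**Figure D1:**
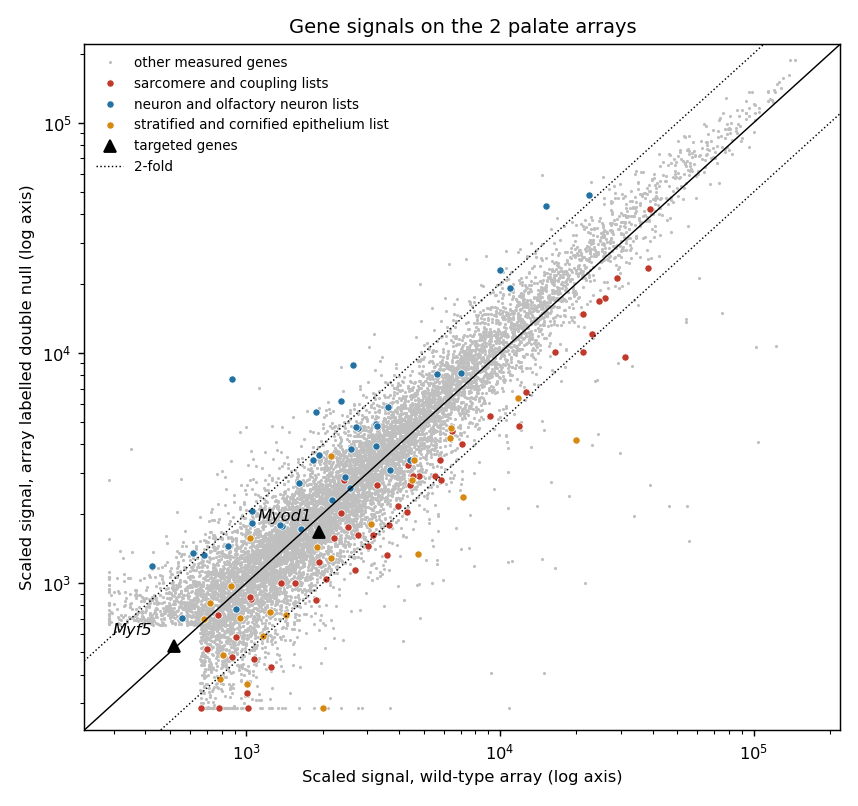
Scaled signal of each measured gene on the wild-type array (x axis, log) and on the array labelled double null (y axis, log), with signals under the floor of 287 drawn at the floor. The solid line marks equal signal and the dotted lines 2-fold. Most sarcomere and coupling genes lie just under the line of equal signal, most neuron genes above it, and Myod1 and Myf5 close to it.

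Levels of the brightest contractile genes, chosen after their values were seen, remained high. Acta1, skeletal alpha-actin, went from 38283 to 23430, at the 98.0th percentile of all probe sets on the array labelled double null. Myh3, embryonic myosin heavy chain, went from 25860 to 17251, Myh8, the perinatal form, from 21160 to 10114, and Mylpf, the fast regulatory light chain, from 24660 to 16804. Taken with the excitation-contraction coupling list, 52 contractile genes were measured, of which 49 were above the floor and 32 at or above the 75th percentile of probe sets on the array labelled double null.

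Genes of excitation-contraction coupling, which links the membrane signal to calcium release, were lower, with a median log2 ratio of -0.75 and 14 of 15 measured genes below 0. Trdn, which anchors the calcium release complex, was at least 3.53-fold lower, Stac3 3.03-fold lower, Jsrp1 at least 2.32-fold lower and Kcnj11 2.28-fold lower. Fkbp1a, a widely expressed gene, had a log2 ratio of 0.11. Of the 15 genes 5 were at least 2-fold lower, against 2 of 14 with scaling on the median signal of the reference genes and 1 of 15 with the floor at the 60th percentile. The list's median lay at the 0.010th percentile of random lists. The muscle energy metabolism list had a median of -0.36 at the 0.71th percentile, which turned to 0.11 when the arrays were scaled on the median signal of the reference genes and lay within the random range in 2 of 13 alternatives. In it Pgam2, muscle phosphoglycerate mutase, was 3.02-fold lower and Ckm, muscle creatine kinase, went from 12145 to 4644 (2.62-fold lower), while Adssl1 was at least 3.91-fold higher, the only member at least 2-fold higher.

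Regulators of myogenesis as a group had a median log2 ratio of -0.08, within the random range of -0.20 to 0.27. Of 22 measured members 1 was at least 2-fold lower and none at least 2-fold higher. Myf6, the regulator also called MRF4, was 2.18-fold lower (971 and 446), and Myog, myogenin, was 1.99-fold lower (1857 and 934). Unc45b, a myosin chaperone, had a log2 ratio of -0.86. Eya1, a transcriptional cofactor of many head tissues, had a log2 ratio of 0.91, and its other probe set was also higher. Pax7, the marker of muscle precursors, chosen after its values were seen, had signals of 633 and 816. At the neuromuscular junction 6 genes were measured with a median of -0.29, within the random range. Chrna1, the acetylcholine receptor alpha subunit, was at least 2.67-fold lower, Dok7 had a log2 ratio of -0.70, Agrn -0.50 and Utrn 0.21, with -1.01 in the other probe set of Utrn. Smooth muscle genes had a median of -0.34, at the 3.06th percentile and within the random range, but below it in 3 of 13 alternatives. Tagln and Actg2 had log2 ratios of -0.94 and -0.86, and Mylk 1.34, with -0.88 in its other probe set.

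**Figure D2:**
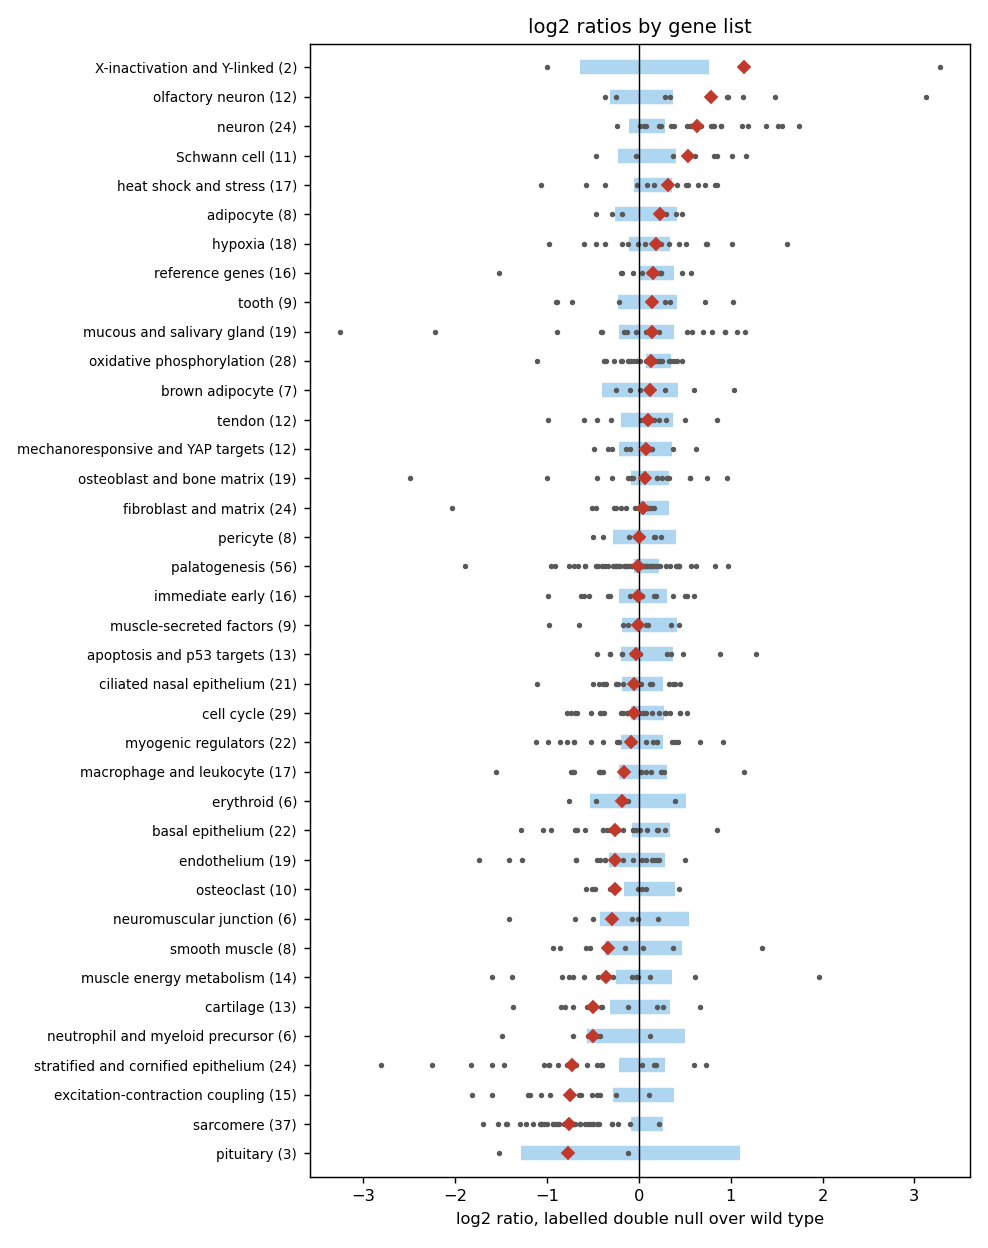
log2 ratio of each measured gene (dots, x axis) by gene list (y axis, number of measured genes in brackets), with the list median (red diamond) and the central 95% of medians of 10000 matched random lists (blue bar). The sarcomere, coupling and cornified epithelium medians lie between -0.76 and -0.73, left of their bars, and the neuron and olfactory neuron medians lie at 0.64 and 0.78, right of theirs.

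Among skeletal and connective tissue lists, the cartilage and osteoclast medians lay below their random ranges and the others within theirs. The osteoblast and bone matrix list had a median of 0.06, within its random range, with 2 of 19 measured genes at least 2-fold lower. These were the osteocyte matrix genes Mepe, at least 5.63-fold lower, and Dmp1, 2.01-fold lower (23284 and 11604), whose other probe sets gave a median of -1.06. Dlx3 and Col1a1, the main bone collagen chain, had log2 ratios of 0.96 and 0.74. The cartilage list was lower, with a median of -0.50 at the 0.16th percentile. Of its 13 measured genes 10 were below 0 but only Col11a2 was at least 2-fold lower (2.59-fold), Chad had -0.85, Mia -0.81 and Matn4 -0.71, and Col2a1, the main cartilage collagen, was the highest at 0.67. The osteoclast list had a median of -0.27 at the 0.55th percentile, which turned to 0.25 under scaling on the median signal of the reference genes and lay within the random range in 2 of 13 alternatives, and none of its 10 measured genes reached 2-fold. Acp5, the osteoclast acid phosphatase, had -0.51. The tendon list had a median of 0.10, which turned to -0.30 at the 1.02th percentile with probe sets without cross-hybridising suffixes, with no gene past 2-fold and Tnmd, tenomodulin, at -0.59. The tooth list had a median of 0.15, with Amtn 2.04-fold higher and the dentine gene Dspp at -0.91. In the fibroblast and matrix list, with a median of 0.05, Dpt, dermatopontin, was 4.10-fold lower (3973 and 970) and the other 23 measured genes lay within 2-fold.

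Genes with known roles in palate formation were mostly within 2-fold. The median log2 ratio over 56 measured genes was -0.01, at the 10.01th percentile of random lists, and 28 were below 0. The 1 gene past 2-fold was Msx1, a homeobox gene whose loss causes cleft palate, which was 3.71-fold lower (9515 and 2561), by 1 measured probe set. The next largest differences were Kif3a at 0.98, Fgfr1 at -0.95, Bmp2 at -0.92, Spry2 at 0.83, Prrx2 at -0.77, Lhx6 at -0.71, Tbx1 at -0.66, Ryk at 0.62, Mn1 at -0.59, Wnt5a at -0.59 and Sox11 at 0.57. Other probe sets of Kif3a, Ryk and Wnt5a had medians of the opposite sign (-0.12, -0.68 and 0.07), and that of Fgfr1 gave -0.25.

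Genes of stratified and cornified epithelium were mostly lower on the array labelled double null. The stratified and cornified epithelium list had a median log2 ratio of -0.73, or 1.66-fold lower, below that of all 10000 random lists. Of its 24 measured genes 6 were at least 2-fold lower, none was at least 2-fold higher and 18 lay in between. With scaling on the median ratio of the reference genes 9 of 26 were lower. Scaling on their median signal gave 5 of 24 lower and 1 higher, with a median of -0.35, and the floor at the 60th percentile gave 4 of 24 lower. Krt4 and Krt13, the keratin pair of non-cornified oral mucosa, were 4.75-fold lower (19880 and 4181) and 3.03-fold lower (7146 and 2358). Lor, loricrin of the cornified envelope, was 3.56-fold lower and Lce1a1 at least 7.02-fold lower. The second probe sets of Krt4, Krt13 and Lor gave -2.19, -1.97 and -3.60. Grhl1 had a log2 ratio of 0.73. Basal epithelium genes had a median of -0.26, at the 0.040th percentile, which turned to 0.16 under scaling on the median signal of the reference genes, with 2 of 22 at least 2-fold lower (Sfn at least 2.43-fold, Lamb3 2.06-fold). Krt15 had -0.96, and Epcam 0.85 with -1.42 in its other probe set. Gland genes went both ways, with a median of 0.14. Smgc and Bpifa2, secretory products of salivary glands, were at least 9.57-fold and at least 4.66-fold lower, whereas Car6, the secreted carbonic anhydrase of saliva, was 2.23-fold higher and Dcpp1 2.09-fold higher. Genes of ciliated nasal epithelium had a median of -0.05, within the random range, and Tekt2 alone passed 2-fold (2.16-fold lower).

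Neuronal genes were higher on the array labelled double null. The neuron list had a median log2 ratio of 0.64, or 1.56-fold higher, and 23 of its 24 measured genes were above 0, of which 6 were at least 2-fold higher. Nefl, the light neurofilament chain, went from 15183 to 43294 (2.85-fold higher), Snap25, a synaptic vesicle fusion protein, was 2.94-fold higher, Elavl4 3.36-fold and Rbfox3 2.61-fold. Gria2 was the member below 0 (-0.24). The olfactory neuron list had a median of 0.78, with 3 of 12 measured genes at least 2-fold higher. Slc17a6, a vesicular glutamate transporter that is not restricted to olfactory neurons, was 8.74-fold higher (878 and 7676) with a log2 ratio of 1.38 in its other probe set, Neurog1 2.79-fold and Cnga2, the olfactory cyclic nucleotide-gated channel, 2.19-fold. Gng13 had 0.97 and Calb2 -0.37. Both medians exceeded those of all 10000 random lists. Of 16 genes of these lists with another measured probe set, 11 were above 0 by the median of the others and 5 below 0, among them Prph (0.52, other -0.99) and Syp (0.01, other -1.30), chosen after their values were seen. Schwann cell genes had a median of 0.54, at the 99.8th percentile, with Dhh 2.24-fold and Fabp7 2.03-fold higher, Mal at 0.85, Ngfr at 0.82 and Sox10 at -0.47. With scaling on the median signal of the reference genes, 12 of 24 neuron, 8 of 12 olfactory neuron and 5 of 12 Schwann cell genes were at least 2-fold higher, and with scaling on their median ratio 5 of 24, 2 of 12 and 1 of 11. Of the pituitary genes 3 were measured, with a median of -0.78 within the random range, Pomc 2.86-fold lower, Lhb at -0.78 and Pitx1 at -0.12.

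Vessel, blood and fat genes showed no list median outside its random range, although the endothelium, macrophage and neutrophil medians each lay below it in 3 of 13 alternatives. In the endothelium list, with a median of -0.26, 3 of 19 measured genes were at least 2-fold lower, namely Tie1 (3.35-fold), Pecam1 (at least 2.66-fold) and Robo4 (2.41-fold), while Emcn had 0.51. Pericyte genes had a median of 0.00 and none passed 2-fold. Erythroid genes had a median of -0.18. In the macrophage and leukocyte list, with a median of -0.16, C1qa was at least 2.94-fold lower and Cd14 2.20-fold higher. Neutrophil and myeloid precursor genes had a median of -0.50, with S100a9 at least 2.81-fold lower. Adipocyte and brown adipocyte genes had medians of 0.23 and 0.13, and Prdm16, a regulator of the brown fat programme, was 2.05-fold higher.

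Lists of cell state also lay within their random ranges, with exceptions in 1 or 2 of 13 alternatives for heat shock, cell cycle, oxidative phosphorylation and muscle-secreted factors. The cell cycle list had a median of -0.05 with none of 29 measured genes past 2-fold. Apoptosis and p53 target genes had a median of -0.03, with Gadd45a 2.42-fold higher. Medians were 0.08 for mechanoresponsive and YAP target genes, -0.01 for immediate early genes, 0.13 for oxidative phosphorylation and -0.01 for factors secreted by muscle. In the hypoxia list, with a median of 0.18, Adm, adrenomedullin, was 3.07-fold and Bnip3 2.02-fold higher, while Vegfa had -0.98. The heat shock and stress list had a median of 0.32 at the 93.8th percentile, with Hspd1 2.09-fold lower and Dnajb1 at 0.85. The reference genes had a median of 0.15, with Eef2 2.88-fold lower and the other 15 within 2-fold.

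Over all genes, 474 (4.22%) were at least 2-fold lower and 394 (3.51%) at least 2-fold higher on the array labelled double null. In a simulation of unchanged genes with the spread seen between probe sets, 5.58% passed 2-fold in either direction, against 7.72% observed. That simulation used the same SD at all signal levels and held no differences between animals or dissections. The gap between these shares therefore does not measure an effect of genotype. Of the lower genes 100 had another measured probe set, and the median of the other probe sets was at least 2-fold lower in 19 and above 0 in 39. Of the higher genes 115 had one, at least 2-fold higher in 23 and below 0 in 28. The balance of directions depended on the scaling: 54.6% of the genes past 2-fold were lower, against 65.0% (573 lower, 308 higher) with the deposited scaling, 12.3% with scaling on the median signal of the reference genes and 75.1% with scaling on their median ratio.

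The lowest ratios belonged to genes outside all 38 lists, and their other probe sets did not follow. Boll was at least 37.9-fold lower, Cacng7 36.5-fold, Rab6b 36.4-fold, Zdhhc14 25.3-fold and E2f5 25.1-fold. Fam71d, Kcnh3, Armc8, Samhd1, 4930563E22Rik, Snrnp27, Cysrt1, Kbtbd13, Pik3cd and Igll1 completed the 15, with folds from 22.7 down to at least 9.94. Signals were high in wild type, for example 122001 for Pik3cd, 104227 for Zdhhc14 and 55381 for Rab6b. Of the 8 genes with another measured probe set, 1 (Kcnh3) was at least 2-fold lower by the median of its other probe sets and 6 had a median above 0.

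The highest ratios were found for Ttr, the thyroxine carrier transthyretin, which was 10.9-fold higher (350 and 3805) and higher in all 4 of its probe sets, for Eif2s3y, at least 9.74-fold higher, and for Slc17a6, Klk1 (6.26-fold) and Cldn34c1 (at least 5.39-fold). They were followed by Rufy2, Opcml, Ttc9, Sema4f, Rnf157, Rnf180, Rassf5, Lrrc8c, Plcxd2 and Slc6a15, with folds from 5.12 to 3.80. Opcml is a neuronal adhesion molecule and Slc6a15 a neuronal amino acid transporter. Of the 7 genes with another measured probe set, all 7 were above 0 by the median of the other probe sets and 4 were at least 2-fold higher.

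**Figure D3:**
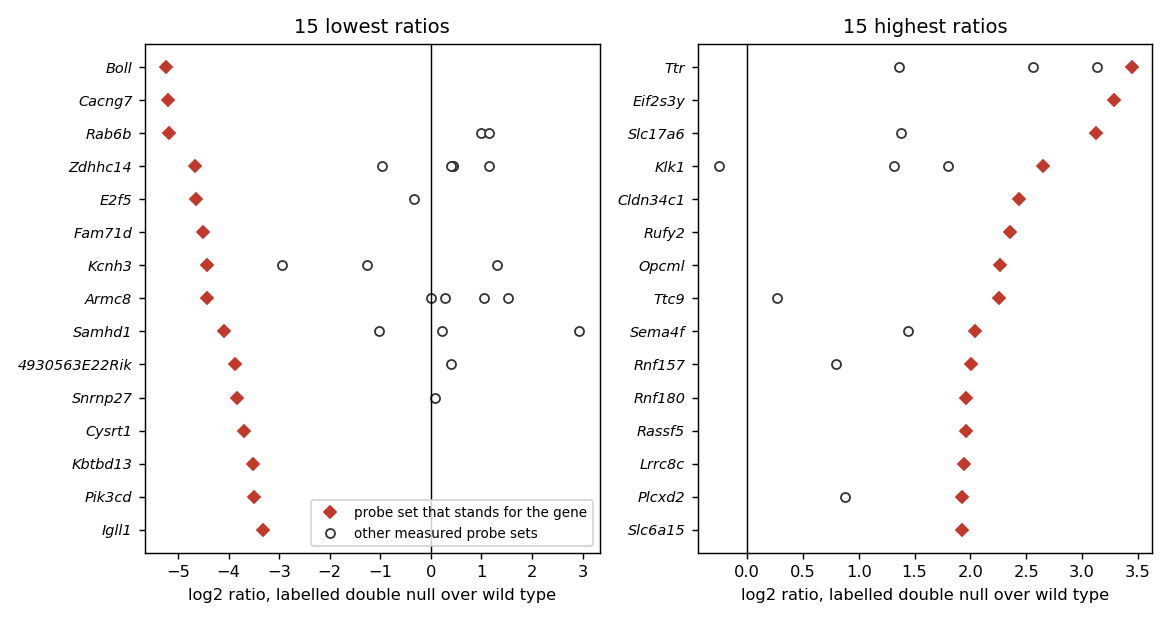
log2 ratio (x axis) of the probe set that stands for each gene (red diamond) and of the gene's other measured probe sets (open circles), for the 15 genes with the lowest ratios (left) and the 15 with the highest (right). Other probe sets of the lowest genes scatter around 0, while those of Ttr, Slc17a6 and Sema4f lie on the same side as the red diamond.

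The samples also differed in sex-linked transcripts and in control probe sets. Eif2s3y, which lies on the Y chromosome, had a signal of 10.8 in wild type and 2794 on the array labelled double null. Xist, expressed from the inactive X chromosome, had 33813 and 16947, with lower signals on the array labelled double null in all 3 of its probe sets. On the array labelled double null both genes were above the level of a measured gene (658). Only 1 Y-linked probe set was measured. The other Eif2s3y probe set had 30.7 and 74.0, under the floor. None of the probe sets of the Y-linked genes Kdm5d and Uty, named after their values were seen, was measured (13.5 to 415 on this array). Among them, probe sets of Kdm5d (34.3 in wild type and 346) and Uty (4.81 and 397, 52.7 and 415) went from under the floor to above it, below 658. In the other direction, 1 Uty probe set went from 325 to 78.9, and the rest were under the floor on both arrays. Eif2s3y and Xist were the 2 measured members of their list, and the median of 1.14 between opposite ratios describes neither. For Gapdh, the control probe sets had log2 ratios of -0.05 at the 3′ end, -0.31 in the middle and -0.45 at the 5′ end, and for Actb 0.18, -0.25 and -0.08. Those for 18S ribosomal RNA were 0.11, 0.48 and 0.74. Within each array the 5′ signals of Gapdh and Actb were far under the 3′ signals. Gapdh had 75927 (3′) and 11277 (5′) in wild type, and 73510 and 8255 on the array labelled double null. Actb had 101600 and 17211 in wild type, and 114956 and 16288 on the other array.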

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

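The bacterial hybridisation controls (bioB, bioC, bioD and cre), which are added to the labelled cRNA in equal amounts and take no part in the comparison of genes, were brighter on the array labelled double null in all 18 probe sets. The median log2 ratio was 0.50, with single probe sets from 0.35 to 0.68, so their signal in data outside the main measurement exceeded that of the wild-type array. Scaling on these controls was not among the alternatives. It would lower the log2 ratios of genes above the floor by about that median. The neuron, olfactory neuron and Schwann cell medians were 0.64, 0.78 and 0.54, so their size above 0 holds only for the scalings used. The poly-A controls had a median of 0.16 over 27 probe sets, from -0.31 to 0.34. No other value met a rule for a closer look, since groups of 1 sample have no outliers and the design has no second contrast.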

How the results depend on the processing

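No paired analysis was possible because each genotype had 1 array, and for the same reason no replicate could be left out. The counts of genes past 2-fold, 474 lower and 394 higher, moved by over 1.5 times under these settings: 203 and 1444 with scaling on the median signal of the reference genes, 264 and 257 with the floor at the 60th percentile, 265 and 197 with the floor value as an offset, 243 and 237 with the filter at the 75th percentile, 1320 and 1486 at 1.5-fold, and 131 and 56 at 3-fold. Settings chosen after seeing the data gave 233 higher (704 lower) with scaling on the median ratio of the reference genes, and 16 and 19 where 2 or more measured probe sets of a gene all passed 2-fold. Higher floors, filters and fold rules lower the count by construction; scaling on the median signal of the reference genes moved the median of all measured genes by 0.40 and scaling on their median ratio by -0.16, and the other settings by less than 0.1.

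Scaling on the median signal of the reference genes turned the medians of muscle energy metabolism to 0.11, of the osteoclast list to 0.25 and of basal epithelium to 0.16; relative to the shift of 0.40 they stayed low, at the 0.97th, 2.14th and 0.015th percentiles. Muscle energy metabolism came within the random range with the mean over probe sets (-0.20, percentile 4.22) and without a filter (-0.05, percentile 4.64), and the osteoclast list with probe sets without cross-hybridising suffixes (-0.25, percentile 4.17) and without a filter (-0.16, percentile 2.76). The X-inactivation and Y-linked list did so with the floor at the 60th percentile (0.54, percentile 92.2) and without a filter (0.40, percentile 94.7). Restricting to probe sets without cross-hybridising suffixes turned Zdhhc14 to 1.16 and Armc8 to 1.05, since another probe set then stood for the gene. The other skeletal muscle medians and the Myf5 and Myod1 ratios moved by less than 0.51, the SD between probe sets. The sarcomere, coupling, cartilage, basal and cornified epithelium, neuron, olfactory neuron and Schwann cell medians stayed outside the random range in all 13 alternatives, of which 1 (median ratio of the reference genes) was chosen after seeing the data. Lists that came outside the random range under an alternative were macrophage and leukocyte (mean over probe sets, -0.41, percentile 0.090; without cross-hybridising suffixes, -0.40; quantile normalization, -0.33), smooth muscle, endothelium and neutrophil (low in 3 alternatives each), heat shock (high in 2, percentiles 99.2 and 97.7), cell cycle (low in 2), and tendon, palatogenesis, neuromuscular junction, oxidative phosphorylation and muscle-secreted factors (low in 1 each). Over the lists of other tissues and states and the named genes, 2532 values moved by less than 0.51, 103 moved by more, and 4 (osteoclast, basal epithelium, Zdhhc14 and Armc8, above) changed sign after having been past 2-fold or outside the random range. Signals near the floor of 287 limit what can be read: 90 of the 474 lower genes and 30 of the 394 higher ones are bounds.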

Other observations

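All tests in this part were chosen after the results were seen. Among 4030 genes with 2 or more measured probe sets, 19 were at least 2-fold higher in every one of them and 16 at least 2-fold lower; with the log2 ratios shuffled over all probe sets 100 times, the highest counts were 10 and 13, and the means 3.61 and 5.64. These genes were chosen after their values were seen. The higher ones included Snap25, Slc17a6 and Stmn3, the neuronal genes Dner, Gpm6a, Ndrg4, Mapk10 and Cacnb4, the sensory channels P2rx3 (1.29 and 1.45) and Scn9a (4 probe sets from 1.10 to 2.09), and Ttr. The lower ones included Krt4, Krt13 and Lor, Tnnt2 (-1.18 and -1.03), Nes, the intermediate filament of progenitor cells (-1.90 and -1.60), Foxm1, a cell cycle transcription factor (-1.48 and -1.39), and Ptgds, prostaglandin D synthase (-2.32 and -1.29).

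Lists of other tissues near the palate, written after the first look at the ratios, gave a median log2 ratio of 0.89 for sensory ganglion neurons, with 8 of 17 measured genes at least 2-fold higher and none lower, above all 10000 random lists. Pou4f1, a transcription factor of sensory neurons, had 1.62, the receptor tyrosine kinase Ret 1.65, the pain-fibre sodium channel Scn11a 1.56 and Ntrk2 -0.59, with a median of 0.84 in its other probe sets. The brightest in wild type were Tac1 (7129 and 10831) and Ntrk2 (8513 and 5665); 15 of the 17 were in no other list. Medians were 0.44 for forebrain, 0.42 for olfactory supporting cells and glands, 0.30 for choroid plexus and 0.07 for retina and pigment cells, each within its random range. In the choroid plexus list only Ttr passed 2-fold.

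The first pattern is that skeletal muscle transcripts remained bright on the array labelled double null. Among the contractile genes compared, the values argue against saturation of bright probe sets as the source of this. Genes of moderate wild-type signal (1147 to 10000) were lower by nearly the same amount as brighter ones. Medians were -0.76 in 29 genes and -0.70 in 12, a difference of -0.0601 (95% bootstrap interval over genes -0.32 to 0.27). Contractile genes with wild-type signals under 1147 were left out, with log2 ratios from -1.82 in Trdn (a bound) to -0.10 in Myl3. A smaller amount of muscle, which would lower all its transcripts by one ratio, was neither excluded nor shown. The SD of 0.44 over 52 contractile genes lay under that of matched random lists (0.46 to 0.86). It was also under the SD of 0.51 between probe sets of one gene. No departure from one ratio beyond that spread was therefore seen in these genes. However, 5 of the 23 lists of other tissues and states with 10 or more measured genes were as tight. Among the other muscle lists energy metabolism had an SD of 0.88 and the regulators a median of -0.08. These values do not decide it either. The SD includes Adssl1 (1.97), whose wild-type signal of 215 was under the floor, and the regulators include genes of other tissues, such as Eya1 (0.91). In the energy list 11 genes were below 0 (Pgam2 -1.60, Ckm -1.39) and 3 above, and among the regulators 13 were below (Myf6 -1.12, Myog -0.99) and 9 above. Lower medians were not particular to muscle. The stratified and cornified epithelium list had -0.73, against -0.76 for the sarcomere list, and cartilage had -0.50. The neuron, olfactory neuron and Schwann cell medians were higher. A wrong label or a mixed sample may also be the source. The Myod1 ratio of -0.22 cannot be told apart from a transcript left by the null allele, because the removed part is not given. Eif2s3y (2794, against 10.8 in wild type) and Xist (16947, against 33813) together on this array may come from more than 1 fetus, of both sexes. Only 1 Y-linked probe set was measured, and the other of Eif2s3y had 74.0. Unmeasured probe sets of Kdm5d (34.3 in wild type and 346) and Uty (4.81 and 397, 52.7 and 415) also rose past the floor, while 1 of Uty fell (325 and 78.9). The sex-linked signals say nothing of genotype. A true loss of part of the muscle in this genotype predicts the same as a smaller amount of muscle, which the SD over contractile genes did not decide. With 1 array per genotype it cannot be told apart from a difference between animals or dissections. How much skeletal muscle this genotype keeps is not given in the labels. The contractile genes, 49 of 52 above the floor on this array, were therefore not set against an expected level. A transcript left by the null allele of Myod1 would bear on the Myod1 probe set and not on theirs.

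The second pattern is the size of the 15 lowest ratios. In the 8 of these genes with another measured probe set, 1 had a median of the others at least 2-fold lower, and the median over the 8 was 0.31 (95% bootstrap interval over genes -0.33 to 0.67), which argues against a lower level of the genes' transcripts as a whole. A probe set that reads something other than the named transcript is a candidate explanation that these values fit. Since the same probe set is on both arrays, what it reads would also have to differ between them, which was not tested. The values do not separate this from any other cause that acts on single probe sets. The 7 genes with no other measured probe set and a change in single isoforms stay open.

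The third pattern is the higher level of neuronal transcripts. A smaller share of muscle would raise every other tissue alike. However, the neuron median was higher by 0.755 (95% bootstrap interval over genes 0.51 to 1.02) than that of other tissues. Theirs was -0.12, over 253 genes from all 19 lists of tissues other than skeletal muscle and nerve. Those lists include the low cartilage, osteoclast and epithelium lists. The interval is over genes of 2 arrays, which are not replicates. Its lower end lay just above the size set, after the results were seen, as too large for a smaller share of muscle. More sensory ganglion tissue in the dissected piece is consistent with the median of 1.09 over 15 ganglion genes that are in no other list, 8 of them at least 2-fold higher, although the list was written after the ratios had been seen, so this test is not independent of them. Forebrain tissue can be neither excluded nor shown with 6 measured genes and a median of 0.44, at the 94.9th percentile. An effect of genotype on innervation stays open and untested.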
